A study of Mus musculus with 27 samples.

How the data were processed

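Intestinal RNA of 27 libraries was analysed, 3 in each of 9 groups taken from the sample labels. The 2 values used per gene and library were whole-number counts and FPKM. The counts were produced by the authors and are used as deposited, as whole numbers per gene and library. How fragments were assigned to genes, the strand setting and the annotation release are not given in the sources used here. The FPKM values were computed by the authors as fragments per kilobase of gene and per 1 M mapped fragments, with 0.0001 in place of 0. The submitters' notes name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 and the mouse build mm8, without saying which program made which value. Of 55141 gene identifiers found in GENCODE vM21, 51957 (94.2%) have the same start and end on GRCm38, so positions are given on GRCm38.

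The table held 55401 genes, of which 23888 had no count in any library. Genes with FPKM of at least 1 in at least 3 libraries were tested, 11118 in all. Total counts per library ran from 57.4 to 87.1 M. Replicates differed by more than counting error, with a chi-square per degree of freedom of 97.5 to 872 between libraries of a group, and the common dispersion of 0.0961 is a biological coefficient of variation of 31.0%. Where a symbol had several entries (134 entries), the one with the highest mean stands for it.

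Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, all 27 libraries in the fit, Benjamini-Hochberg adjustment within each comparison). Adjusted p-values of genes are from edgeR unless another tool is named. The plan written before the data were examined assumed limma on log2(FPKM + 1). The table holds counts as well, so edgeR became the test, and limma is given as an alternative. There were 14 comparisons of 2 groups and 2 interactions, which set the effect of CBLB502 with radiation against its effect without. Gene lists (38 written before the data were examined, 35 with enough tested members) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2. The preset correlation was 0.01, and a correlation estimated per list was run beside it. The score of a list in a library is the mean over its tested genes of log2 CPM minus that gene's mean over all libraries.

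The genes named were set by a rule fixed before the data were examined. In each comparison of 2 groups it takes the 6 largest rises and 6 largest falls among called genes whose 3 libraries of one group all lie above the 3 of the other. The higher group must have a mean FPKM of at least 5. Predicted and clone-named genes, pseudogenes and immunoglobulin or T cell receptor segments are left out. For the interactions the rule has no condition on overlap. It adds up to 4 members with the smallest adjusted p of each list described. It also adds Cdkn1a, Mdm2, Lgr5, Olfm4, Mki67, Clu, Reg3b, Reg3g, Tlr5 and Ms4a1, of which Lgr5, Tlr5 and Ms4a1 were below the filter. A gene that the rule names in the 15 Gy interaction is not reported here.

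The alternatives were no filter on low values (31509 genes), median-ratio scaling, the replicate number as a block, limma on log2(FPKM + 0.1) and on quantile-normalized values, the compared groups fitted alone, and each library left out. Limma on log2(FPKM + 1), the test of the plan, was run as well. Chosen after seeing the data were DESeq2 1.42.0, mitochondrial genes left out (11081 genes), the mitochondrial share or the proximal score as a covariate, and a fit without the 6 libraries of 6 Gy at 24 h. On simulated data, 200 of 11118 genes were changed in the libraries of 15 Gy 24 h but not in control. They were drawn from genes with a mean count of at least 20. Changes of 1.5, 2 and 4-fold were recovered by edgeR for 17.9, 55.2 and 83.3% of genes, with 5 unchanged genes among 109 calls. DESeq2 recovered 67.2% of the 2-fold changes with 29 unchanged genes among 153 calls. Limma on log2(FPKM + 1) recovered 22.4% with 6 among 65, but its simulated FPKM values were scaled far below the 1 added to them. Its median error was 0.984 in log2 at 2-fold, so this run does not measure how limma performs. In the 14 comparisons of 2 groups edgeR recovered 32.8 to 56.7% of the 2-fold changes, and in the interactions 14.9 and 16.4%. Unchanged genes made up 2.08 to 8.91% of its calls in the 14 comparisons, with the highest share at 6 Gy 24 h against control. In the 15 Gy and 6 Gy interactions they made up 8.2 and 3.64%. A list of 20 genes changed 2-fold was called by camera, and 0 of 20 random lists were. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called without a change. No library was left out of the fit.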

Results

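RNA from the intestine of male C57BL/6 mice aged 6 to 8 weeks was sequenced in 27 libraries, in 9 groups of 3. A control group stood beside groups given 60Co gamma rays at 72 R/min. The doses were 6 Gy, sampled at 6 h or 24 h, and 15 Gy, sampled at 6 h, 24 h or 3 d. CBLB502 is a flagellin-derived protein that activates Toll-like receptor 5 and is studied as a radioprotectant. It was given at 0.2 mg per kg alone or with 15 Gy (0.5 h before irradiation), and also with 6 Gy, and these groups were sampled at 24 h. The design text of the series counts 7 groups of 10 mice, while the sample labels hold 9 groups. It is not stated whether each library is a separate mouse, so the p-values measure the spread between these libraries.

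Total counts per library ran from 57.4 to 87.1 M. The control libraries held 75.5, 86.9 and 78.3 M. Those of 6 Gy at 6 h held 75.7, 76.6 and 75.1 M, and those of 6 Gy at 24 h 57.4, 67.3 and 58.5 M. For 15 Gy the totals were 83.6, 87.1 and 80.5 M at 6 h, 78.9, 80.5 and 78.8 M at 24 h, and 79.0, 81.4 and 82.2 M at 3 d. CBLB502 alone had 60.6, 79.7 and 83.7 M, with 15 Gy 79.3, 86.5 and 83.1 M, and with 6 Gy 68.5, 66.4 and 62.1 M.

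Levels below are counts per 1 M scaled by TMM (CPM, mean ± SD) and changes are log2 fold changes ± SE, with n = 3 libraries per group. Called genes had an adjusted p under 0.05 in edgeR among 11118 genes tested, and rose or fell is written of called genes. Medians of gene lists are log2 fold changes. A second count, adjusted over the list alone, is given where it differs from the count over all genes. A gene with 0 counts in a group may reach 0.0121 to 0.0156 CPM there (3 counts over the group), and such floors cover counting error only. The genes with the largest changes were taken where all 3 libraries of one group lay above all 3 of the other, which chance gives for 10% of genes.

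Several genes recur below, with positions on GRCm38. Ccng1 (ENSMUSG00000020326) lies on chromosome 11 from 40748552 to 40755311. Phlda3 (ENSMUSG00000041801) lies on chromosome 1 from 135766119 to 135769136. Fut2 (ENSMUSG00000055978) lies on chromosome 7 from 45648591 to 45666394. Gml2 (ENSMUSG00000068600) lies on chromosome 15 from 74819071 to 74834871. Reg3b (ENSMUSG00000071356) lies on chromosome 6 from 78370657 to 78373466. Duox2 (ENSMUSG00000068452) lies on chromosome 2 from 122279247 to 122298449. Lct (ENSMUSG00000026354) lies on chromosome 1 from 128284756 to 128328318. Clu (ENSMUSG00000022037) lies on chromosome 14 from 65968483 to 65981547.

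The 6 libraries of 6 Gy at 24 h, with and without CBLB502, stood apart from the other 21. The pancreatic amylase gene Amy2a3 reached 419 ± 692 CPM at 6 Gy and 281 ± 206 CPM with CBLB502, against 0 counts in control. The collagen gene Col1a1 stood at 21.9 ± 5.38 and 16.6 ± 6.97 CPM against 0.278 ± 0.206 CPM. Marker scores are the mean centred log2 CPM of a list. For exocrine pancreas they were 5.27 ± 3.81 and 6.60 ± 1.73, against -2.46 ± 0.20 in control. The mean pancreatic score was also above control at 6 Gy 6 h (0.03 ± 1.28), 15 Gy 24 h (-0.55 ± 2.11) and 15 Gy 24 h with CBLB502 (-1.57 ± 0.92). In each of the last 2 groups 1 library lay below every control library (-2.84 at 15 Gy 24 h). Fibroblast scores, over 3 tested genes of 16 listed, were 3.57 ± 0.45 and 3.88 ± 0.49, against -1.21 ± 1.32.

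**Figure D1:**
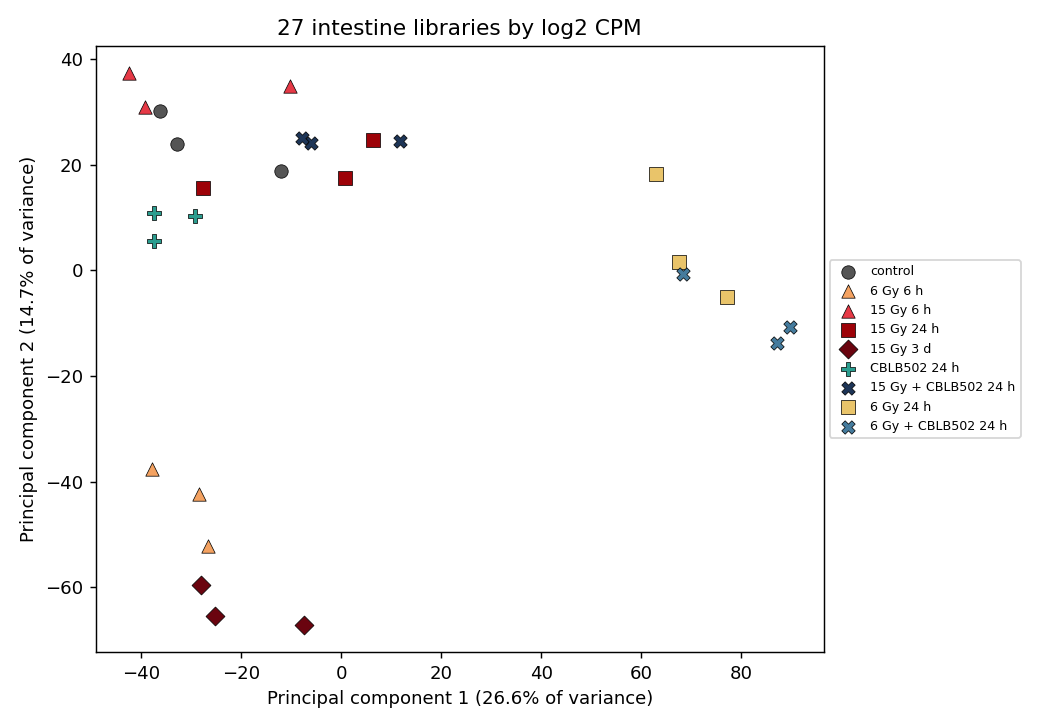
Principal components 1 and 2 of log2 CPM for the 27 libraries, coloured by group, with 26.6% and 14.7% of the variance. The 6 libraries of 6 Gy at 24 h with and without CBLB502 lie apart on component 1, and those of 6 Gy at 6 h and 15 Gy at 3 d lie low on component 2.

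Clock genes, the mitochondrial share and markers of position along the gut also differed between groups. The clock score is the mean log2 CPM of Arntl, Npas2 and Nfil3 minus that of Dbp, Per1, Per2, Per3, Cry2 and Tef, centred over the libraries. It was -2.58 ± 0.35 in control, 2.51 ± 0.61 at 6 Gy 6 h and -2.45 ± 0.87 at 15 Gy 6 h. At 15 Gy it was 1.20 ± 2.55 at 24 h (4.14 in replicate 1 and -0.28 in both others), 2.19 ± 0.76 at 3 d and 2.35 ± 1.38 with CBLB502. Mitochondrially encoded genes took 14.0 ± 3.33% of counts in control, 19.7 ± 7.94% at 6 Gy 6 h and 6.82 ± 2.22% at 15 Gy 6 h. The score of proximal small intestine genes was -1.07 ± 0.24 in control and 1.17 ± 0.68 with CBLB502.

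**Figure D2:**
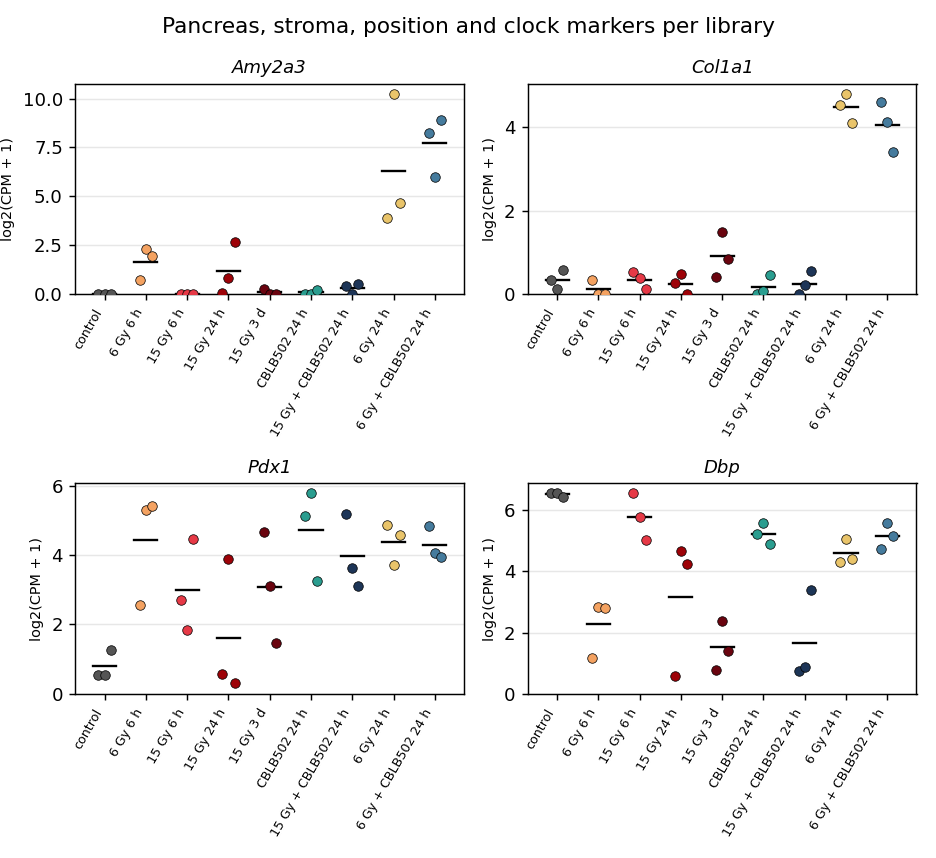
Levels of Amy2a3 (pancreas), Col1a1 (fibroblasts), Pdx1 (proximal gut and pancreas) and Dbp (clock output) as log2(CPM + 1) per library by group, with lines at group means of 3. Pdx1 is 32.3 ± 23.0 CPM with CBLB502 against 0.778 ± 0.553 CPM in control, and Dbp is 2.19 ± 1.80 CPM at 15 Gy 3 d against 91.0 ± 4.76 CPM.

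The comparison of 6 Gy at 6 h with control asked what the lower dose had changed early. Of 26 enterocyte genes 21 fell. The list had a median of -1.01 (camera adjusted p = 1.2e-10, adjusted p = 0.0165 with an estimated correlation). Lactase (Lct) fell from 2764 ± 385 to 921 ± 88.0 CPM (-1.59 ± 0.21, adjusted p = 9e-06). Mttp, which loads lipid onto lipoproteins, fell from 4606 ± 154 to 2370.5 ± 246 CPM (-0.96 ± 0.11, adjusted p = 1.9e-06). Among 26 targets of p53, 14 rose and 4 fell (15 higher and 4 lower adjusted over the list alone). These targets had a median of 0.64 (camera adjusted p = 0.00531, adjusted p = 0.294 with an estimated correlation). Ccng1, a cyclin induced by p53, rose from 19.5 ± 2.38 to 114 ± 7.25 CPM (2.55 ± 0.16, adjusted p = 6.6e-10). The nuclease gene Aen rose from 1.25 ± 0.323 to 6.99 ± 2.82 CPM, while Sesn1 fell (-1.35 ± 0.19, adjusted p = 1.5e-05). Cdkn1a, the p53-induced cell cycle inhibitor, was not called (-0.30 ± 0.18, adjusted p = 0.246).

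Fut2, which adds fucose to glycans of the gut surface, rose from 1.89 ± 0.434 to 301 ± 22.4 CPM at 6 Gy 6 h (7.32 ± 0.56, adjusted p = 1e-08). The neutrophil antigen gene Ly6g was at least 404-fold higher, at 5.87 ± 0.995 CPM against 0 counts. Pck1 of gluconeogenesis (-5.67 ± 0.71, adjusted p = 4.6e-06) and the drug exporter Abcb1a (-6.05 ± 0.34, adjusted p = 1.9e-10) were among the largest falls. Of 14 goblet cell genes 1 rose and 9 fell (1 higher and 11 lower adjusted over the list alone), with Tff3 at 376 ± 231 against 1006 ± 357 CPM. Goblet genes had a median of -1.33 (camera adjusted p = 0.00013, adjusted p = 0.439 with an estimated correlation). Of 11 tuft cell genes 8 rose, and this list had a median of 1.10 (camera adjusted p = 0.00065, adjusted p = 0.439 with an estimated correlation). Of 13 enteroendocrine genes 7 rose, with Cck at 70.6 ± 29.8 against 11.3 ± 2.33 CPM. That list had a median of 0.78 (camera adjusted p = 0.00531, adjusted p = 0.439 with an estimated correlation). The antimicrobial list was not called by camera, but 4 of its 11 genes rose. Reg3b, a bactericidal lectin, went from 8927 ± 3241 to 26073 ± 3834 CPM (1.55 ± 0.44, adjusted p = 0.0114). The clock list had a median of -2.24 (camera adjusted p = 0.00531, adjusted p = 0.0844 with an estimated correlation) in the same libraries. Of 16 pancreatic genes 1 rose, the elastase gene Cela2a (0 adjusted over the list alone), which is named after its values were seen. Their median was 3.99 with 8 at their bound, and camera did not call the list (adjusted p = 0.0533). In all 3163 genes were called, 1462 higher and 1701 lower. The majority turned with limma on log2(FPKM + 1), to 1409 higher and 1127 lower.

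For 15 Gy at 6 h against control the question was the same at the higher dose. Of 26 targets of p53 15 rose and 1 fell, and the list had a median of 0.89 (camera adjusted p = 5.4e-06, adjusted p = 0.077 with an estimated correlation). Ccng1 rose from 19.5 ± 2.38 to 52.6 ± 13.1 CPM (1.43 ± 0.15, adjusted p = 9.2e-07) and the kinase Plk2 from 3.09 ± 1.24 to 14.5 ± 2.73 CPM (2.23 ± 0.29, adjusted p = 7.8e-06). Phlda3, an inhibitor of Akt, stood at 4.13 ± 0.389 against 0.0178 ± 0.0309 CPM. Mdm2, the p53 ubiquitin ligase, fell (-0.49 ± 0.17, adjusted p = 0.0375), and Cdkn1a was not called (0.41 ± 0.18, adjusted p = 0.0929). The epithelial oxidase gene Duox2 fell (-2.65 ± 0.99, adjusted p = 0.0488), though not when adjusted over the list alone. Of 26 enterocyte genes 5 rose and 2 fell: trehalase (Treh) rose (0.93 ± 0.17, adjusted p = 0.0004) and sucrase-isomaltase (Sis) fell (-1.41 ± 0.34, adjusted p = 0.00349). Of 13 mitochondrially encoded genes 8 fell (9 lower adjusted over the list alone), and they had a median of -1.18 (camera adjusted p = 0.0209, adjusted p = 0.994 with an estimated correlation). Tuft cell genes had a median of 0.89 (camera adjusted p = 0.00624, adjusted p = 0.994 with an estimated correlation). In all 3219 genes were called (1352 higher, 1867 lower), and 1532 with the 6 compared libraries fitted alone.

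Set directly against each other, the doses at 6 h gave 4800 called genes, 2246 higher and 2554 lower at 15 Gy. Of 26 enterocyte genes 21 rose and 1 fell, and they had a median of 1.19 (camera adjusted p = 2.6e-08, adjusted p = 0.0496 with an estimated correlation). Lct stood at 4348 ± 679 against 921 ± 88.0 CPM and Treh at 1551 ± 246 against 484 ± 60.4 CPM. Of 14 goblet cell genes 9 rose (10 higher adjusted over the list alone), and these had a median of 1.28 (camera adjusted p = 0.00147, adjusted p = 0.854 with an estimated correlation). Of 11 antimicrobial genes 8 fell at 15 Gy. The list had a median of -2.66 (camera adjusted p = 0.0112, adjusted p = 0.685 with an estimated correlation). Reg3b stood at 5991 ± 3658 against 26073 ± 3834 CPM, Duox2 at 32.3 ± 42.3 against 864 ± 359 CPM and the lipocalin Lcn2 at 0.96 ± 0.78 against 74.7 ± 57.6 CPM. Fut2 was lower (-7.38 ± 0.56, adjusted p = 4.8e-09), Ly6g was at least 435-fold lower, and Pck1 was higher (5.33 ± 0.70, adjusted p = 3.5e-06). Ccng1 was lower at the higher dose (-1.12 ± 0.15, adjusted p = 4.3e-06) and Cdkn1a higher (0.71 ± 0.18, adjusted p = 0.00333). The mitochondrially encoded genes moved with the same groups (10 of 13 fell) and had a median of -1.60 (camera adjusted p = 0.0111, adjusted p = 0.924 with an estimated correlation).

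**Figure D3:**
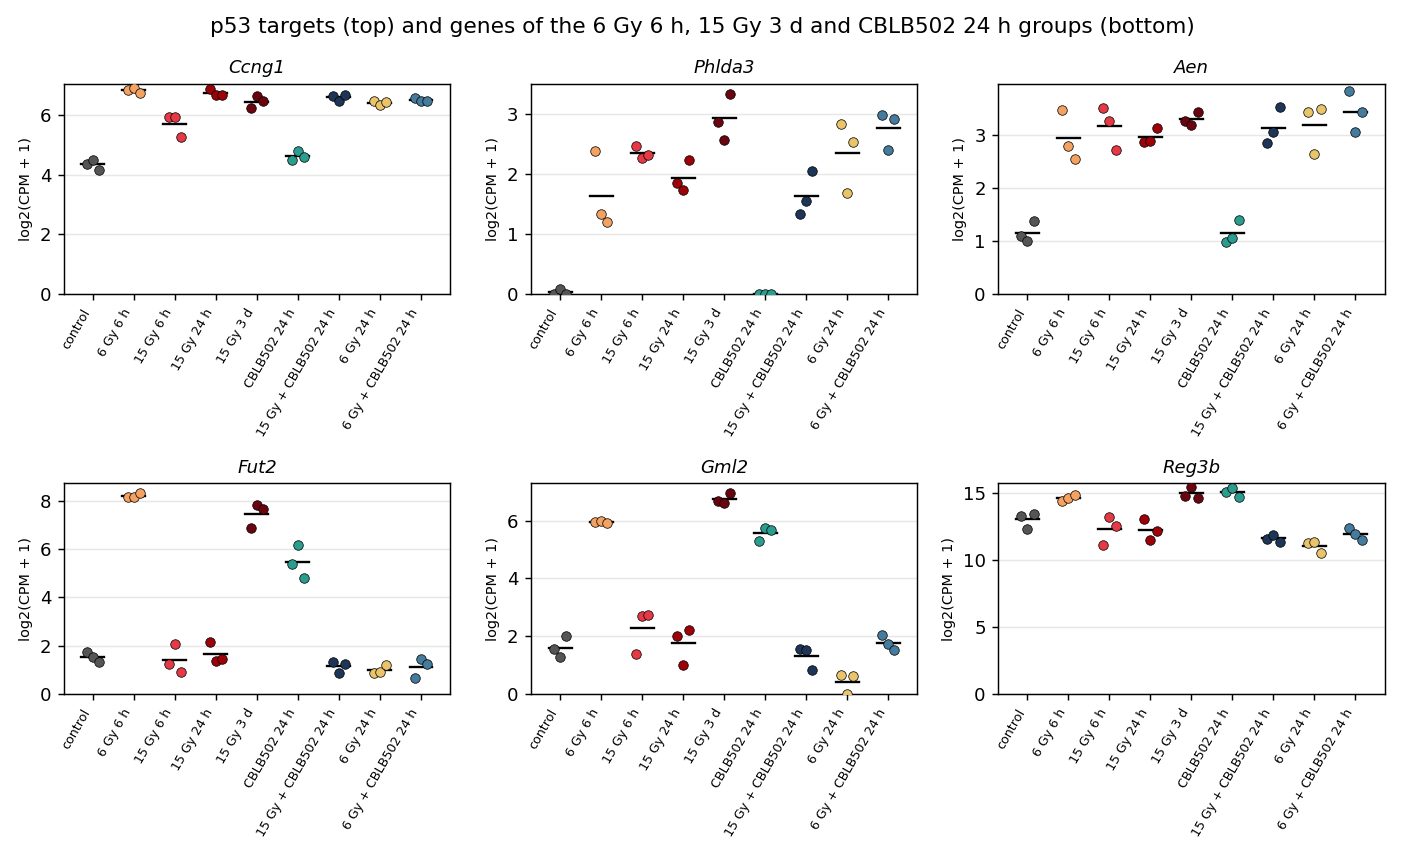
Levels of Ccng1, Phlda3 and Aen (p53 targets) and of Fut2, Gml2 and Reg3b as log2(CPM + 1) per library by group, with lines at group means of 3. Ccng1 is 19.5 ± 2.38 CPM in control and 52.6 ± 13.1 to 114 ± 7.25 CPM in the 7 irradiated groups, while Fut2 is high at 6 Gy 6 h (301 ± 22.4 CPM), 15 Gy 3 d (184 ± 58.0 CPM) and with CBLB502 (46.5 ± 23.0 CPM).

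At 24 h after 6 Gy, the comparison with control asked what remained or had developed after 1 day. These libraries are among the 6 that stood apart, so radiation cannot be told apart here from a batch or from tissue make-up. Of 11 antimicrobial genes 8 fell, and the list had a median of -3.23 (camera adjusted p = 0.00017, adjusted p = 0.154 with an estimated correlation). Reg3g fell from 5458 ± 2217 to 846 ± 276 CPM (-2.69 ± 0.48, adjusted p = 0.00037). Nos2, the inducible nitric oxide synthase, fell from 59.0 ± 6.80 to 0.884 ± 0.65 CPM. Of 16 DNA replication genes 6 rose, with Mcm5 at 4.03 ± 2.61 against 0.581 ± 0.131 CPM. Replication genes had a median of 0.82 (camera adjusted p = 0.0173, adjusted p = 0.349 with an estimated correlation). Of 10 mitosis genes 5 rose (6 higher adjusted over the list alone), with Plk1 at 6.66 ± 1.74 against 2.39 ± 0.284 CPM. Mitosis genes had a median of 1.51 (camera adjusted p = 0.0228, adjusted p = 0.584 with an estimated correlation). The stem cell factor Ascl2 was at least 58.6-fold higher than the control, which had 0 counts. Of 17 Paneth cell genes 6 rose, with lysozyme 1 (Lyz1) at 177 ± 134 against 33.2 ± 16.7 CPM. Paneth genes had a median of 2.33 (camera adjusted p = 0.0445, adjusted p = 0.729 with an estimated correlation). Of 26 enterocyte genes 18 fell (19 lower adjusted over the list alone), and enterocyte genes had a median of -0.76 (camera adjusted p = 5.7e-07, adjusted p = 0.108 with an estimated correlation). The sodium-glucose transporter Slc5a1 fell (-1.41 ± 0.18, adjusted p = 2.1e-05), as did apolipoprotein Apoa1 (-1.40 ± 0.24, adjusted p = 0.00029).

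Targets of p53 also moved at 6 Gy 24 h, where 15 rose and 4 fell (15 higher and 5 lower adjusted over the list alone) of 26. The p53 list had a median of 0.74 (camera adjusted p = 0.00017, adjusted p = 0.11 with an estimated correlation). Ccng1 stood at 85.2 ± 4.16 against 19.5 ± 2.38 CPM, and Cdkn1a fell from 413 ± 10.9 to 236 ± 23.4 CPM (-0.81 ± 0.18, adjusted p = 0.0024). Of 8 DNA repair genes 6 rose (7 higher adjusted over the list alone), and the list had a median of 1.07 (camera adjusted p = 0.00212, adjusted p = 0.154 with an estimated correlation). All 16 measured pancreatic enzyme genes rose, with a median of 12.84 when the 8 at 0 counts in control stand at their bound. Amy2a3 was at least 28800-fold higher, and its SD exceeded its mean. Fibroblast genes (3 of 3 tested, of 16 listed) and smooth muscle genes (5 of 9, 7 adjusted over the list alone) rose in the same libraries. A gene high only in the libraries that stood apart passes the filter, so these counts and that of the pancreatic genes may partly follow from it. In all 3669 genes were called (1843 higher, 1826 lower). With limma on log2(FPKM + 1) there were 6241, of which 93.0% were higher, while the median of all genes moved by 0.38. With DESeq2 and median-ratio scaling the majority was lower (2147 of 4105 and 1972 of 3688).

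At 24 h after 15 Gy, 549 genes were called against control (292 higher, 257 lower). Of 26 targets of p53 15 rose (16 higher and 1 lower adjusted over the list alone), and they had a median of 0.65 (camera adjusted p = 8.4e-14, adjusted p = 0.00141 with an estimated correlation). Ccng1 rose from 19.5 ± 2.38 to 108 ± 9.06 CPM (2.46 ± 0.16, adjusted p = 5e-09) and Plk2 from 3.09 ± 1.24 to 18.9 ± 3.79 CPM (2.61 ± 0.29, adjusted p = 3.1e-05). Mbl2, a mannose-binding lectin of complement, rose from 44.0 ± 6.11 to 648 ± 219 CPM (3.88 ± 0.64, adjusted p = 0.00159). Bco1, which cleaves beta-carotene, fell from 42.4 ± 1.57 to 1.70 ± 1.13 CPM (-4.64 ± 0.66, adjusted p = 0.00032). Of 27 interferon-stimulated genes 4 fell (1 higher and 13 lower adjusted over the list alone), with Gbp2 at 1.99 ± 0.733 against 8.19 ± 1.39 CPM. Interferon-stimulated genes had a median of -1.06 (camera adjusted p = 2.8e-09, adjusted p = 0.408 with an estimated correlation). Of 12 T cell genes 2 fell (10 lower adjusted over the list alone), with Cd3d at 1.85 ± 0.456 against 5.43 ± 2.51 CPM. T cell genes had a median of -1.21 (camera adjusted p = 6.8e-07, adjusted p = 0.408 with an estimated correlation). Of 11 antimicrobial genes 0 were called, with a camera adjusted p of 0.209. Of 16 pancreatic genes 0 were called, with a median of 4.35 when 8 stand at their bound, but camera called the list higher (adjusted p = 0.0216, 0.83 with an estimated correlation). Its adjusted p was 0.0648 and 0.303 without replicate 2 or 3 of 15 Gy 24 h. The count of 549 depended on the control libraries and the fit. It was 216 and 285 without control replicate 1 or 2, and 328, 305 and 365 without replicate 1, 2 or 3 of 15 Gy 24 h. With the 6 compared libraries fitted alone it was 12, with limma on log2(FPKM + 1) 241 and with DESeq2 1071 (583 lower).

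The 15 Gy libraries were also set against those of 6 Gy at 24 h. The 6 Gy libraries are among the 6 that stood apart, so dose cannot be told apart here from a batch or from tissue make-up. Of 10 mitosis genes 8 fell (9 lower adjusted over the list alone), and they had a median of -1.97 (camera adjusted p = 2.2e-05, adjusted p = 0.26 with an estimated correlation). Of 16 DNA replication genes 6 fell (7 lower adjusted over the list alone), and these had a median of -0.99 (camera adjusted p = 0.00012, adjusted p = 0.173 with an estimated correlation). Plk1 stood at 2.18 ± 0.103 against 6.66 ± 1.74 CPM and the stem cell gene Olfm4 at 0.905 ± 0.92 against 15.0 ± 13.1 CPM. Of 11 antimicrobial genes 6 rose (9 higher adjusted over the list alone), with Reg3g at 3474 ± 2099.7 against 846 ± 276 CPM. Antimicrobial genes had a median of 2.71 (camera adjusted p = 0.00011, adjusted p = 0.173 with an estimated correlation). T cell genes had a median of -1.13 (camera adjusted p = 0.00027, adjusted p = 0.526 with an estimated correlation). Plasma cell genes had a median of -3.05 (camera adjusted p = 0.0153, adjusted p = 0.397 with an estimated correlation), with Igha at 33.0 ± 33.9 against 421 ± 244 CPM. Of 26 enterocyte genes 9 rose (14 higher and 1 lower adjusted over the list alone), a direction that turned with quantile-normalized FPKM (camera adjusted p = 0.789). All 16 pancreatic genes were lower at 15 Gy, with a median of -8.54. In all 1736 genes were called between the doses at 24 h (955 higher, 781 lower). The count was 714 and 943 without replicate 1 or 3 of 15 Gy 24 h, and 773 and 862 without replicate 1 or 3 of 6 Gy 24 h. It was 307 with the 6 libraries fitted alone. With limma on log2(FPKM + 1) it was 4449, of which 3.9% were higher, while the median of all genes moved by -0.33.

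At 3 d after 15 Gy, the comparison with control asked how the tissue stood later. Of 17 genes of regenerating, fetal-like epithelium 14 rose (14 higher and 2 lower adjusted over the list alone). They had a median of 1.79 (camera adjusted p = 2.5e-06, adjusted p = 0.151 with an estimated correlation). Amphiregulin (Areg) rose from 39.3 ± 4.66 to 136 ± 18.1 CPM (1.79 ± 0.20, adjusted p = 1.8e-06) and clusterin (Clu) from 4.14 ± 1.97 to 49.4 ± 19.3 CPM (3.58 ± 0.76, adjusted p = 0.00127). Of 13 crypt stem cell genes 9 rose, with Sox9 at 15.6 ± 0.825 against 1.51 ± 0.603 CPM. Crypt genes had a median of 1.68 (camera adjusted p = 0.00046, adjusted p = 0.151 with an estimated correlation). Of 11 tuft cell genes 10 fell (1 higher and 10 lower adjusted over the list alone), and tuft genes had a median of -1.59 (camera adjusted p = 8.8e-07, adjusted p = 0.151 with an estimated correlation). Of 26 enterocyte genes 1 rose and 17 fell (1 higher and 19 lower adjusted over the list alone), and the list had a median of -0.84 (camera adjusted p = 7e-07, adjusted p = 0.0969 with an estimated correlation). Lct fell from 2764 ± 385 to 469 ± 83.6 CPM (-2.56 ± 0.22, adjusted p = 4.4e-08). Of 12 T cell genes 7 fell (9 lower adjusted over the list alone), and T cell genes had a median of -1.30 (camera adjusted p = 0.00092, adjusted p = 0.666 with an estimated correlation). Of the only 3 B cell genes tested, from 19 listed, 2 fell, with Spib at 0.949 ± 0.352 against 5.78 ± 0.201 CPM. Toll-like receptor pathway genes had a median of 0.49 (camera adjusted p = 0.017, adjusted p = 0.166 with an estimated correlation), with Tlr1 at 15.6 ± 4.98 against 0.735 ± 0.346 CPM.

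The p53 targets still differed from control at 3 d, where 14 rose and 3 fell (15 higher and 3 lower adjusted over the list alone) of 26. Their list had a median of 0.71 (camera adjusted p = 0.00012, adjusted p = 0.0985 with an estimated correlation). Of 17 Paneth cell genes 6 rose, with the protease Mmp7 at 60.8 ± 35.8 against 4.08 ± 0.4 CPM. Paneth genes had a median of 2.0 (camera adjusted p = 0.0115, adjusted p = 0.754 with an estimated correlation). Fut2 rose (6.61 ± 0.55, adjusted p = 3.1e-08) and Reg3b rose (1.92 ± 0.45, adjusted p = 0.00275), while Reg3a fell (-1.83 ± 0.33, adjusted p = 0.00029). The nuclear receptor gene Nr0b2 was at least 803-fold higher than the control, which had 0 counts. Slc5a4a and Slc5a4b of the sodium-glucose transporter family fell (-6.34 ± 0.48, adjusted p = 8.5e-09 and -6.72 ± 0.41, adjusted p = 6e-10). The neutrophil list, with only 3 of its 15 genes tested, had a median of 2.25 (camera adjusted p = 0.00633, adjusted p = 0.0969 with an estimated correlation). Clock genes had a median of -1.95 (camera adjusted p = 0.0141, adjusted p = 0.136 with an estimated correlation) in the same libraries. In all 3273 genes were called (1542 higher, 1731 lower), and 2142 with the 6 compared libraries fitted alone. Of the calls by limma on log2(FPKM + 1) 73.8% were higher instead of 47.1%, while the median of all genes moved by 0.16.

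**Figure D4:**
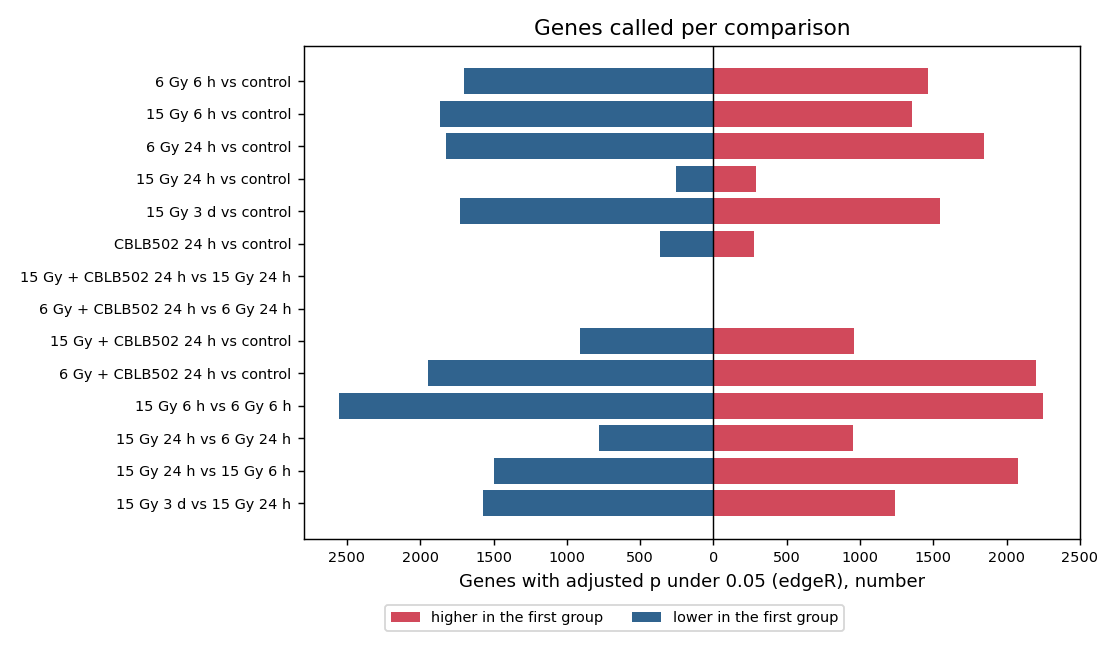
Numbers of genes called higher (bars to the right) and lower (bars to the left) at an adjusted p under 0.05 in edgeR for the 14 comparisons of 2 groups. The counts run from 0 for CBLB502 in irradiated mice at either dose to 4800 for 15 Gy against 6 Gy at 6 h.

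The comparison of 24 h with 6 h after 15 Gy asked what changed within the 1st day. Of 19 cholesterol genes 9 fell (10 lower adjusted over the list alone), with Mvk at 6.55 ± 0.915 against 25.7 ± 6.97 CPM. Cholesterol genes had a median of -1.26 (camera adjusted p = 0.00205, adjusted p = 0.96 with an estimated correlation). Of 12 glucocorticoid-induced genes 7 fell (9 lower adjusted over the list alone), with metallothionein 1 (Mt1) at 30.1 ± 8.39 against 136 ± 22.7 CPM. They had a median of -1.35 (camera adjusted p = 0.00926, adjusted p = 0.96 with an estimated correlation). Tuft cell genes had a median of -0.79 (camera adjusted p = 0.0236, adjusted p = 0.96 with an estimated correlation). Ccng1 rose further from 52.6 ± 13.1 to 108 ± 9.06 CPM (1.03 ± 0.15, adjusted p = 2.4e-05), while Cdkn1a fell (-0.85 ± 0.18, adjusted p = 0.00113). Mitochondrially encoded genes had a median of 1.35 (camera adjusted p = 0.00926, adjusted p = 0.96 with an estimated correlation). Of 3575 genes called 2078 were higher and 1497 lower at 24 h, and 2024 were called with the 6 libraries fitted alone.

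From 24 h to 3 d, 11 of 17 regenerating-epithelium genes rose (11 higher and 1 lower adjusted over the list alone), and the list had a median of 1.58 (camera adjusted p = 1.4e-07, adjusted p = 0.159 with an estimated correlation). Ly6a, the stem cell antigen Sca-1, stood at 33.0 ± 7.52 against 0.819 ± 0.178 CPM. Of 27 interferon-stimulated genes 15 rose (18 higher adjusted over the list alone), with Oas2 at 87.3 ± 49.7 against 7.93 ± 1.73 CPM. Interferon genes had a median of 1.23 (camera adjusted p = 2e-06, adjusted p = 0.603 with an estimated correlation). Tuft cell genes had a median of -2.02 (camera adjusted p = 6.2e-08, adjusted p = 0.159 with an estimated correlation). Enterocyte genes had a median of -0.46 (camera adjusted p = 0.00125, adjusted p = 0.205 with an estimated correlation), with Lct at 469 ± 83.6 against 3150.1 ± 146 CPM. Fut2 rose (6.35 ± 0.54, adjusted p = 3.4e-08), as did Ggh, a folate hydrolase (6.30 ± 0.39, adjusted p = 5.1e-10). In all 2813 genes were called (1241 higher, 1572 lower), and 1663 with the 6 libraries fitted alone. Limma on log2(FPKM + 1) gave calls of which 62.5% were higher instead of 44.1%.

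CBLB502 against control asked what giving the TLR5 agonist changed without radiation. The design text names PBS as the control for CBLB502, but the control libraries are not labelled as given PBS, so an effect of the injection or vehicle is not set apart here. Reg3b rose from 8927 ± 3241 to 35651 ± 8016 CPM (2.0 ± 0.45, adjusted p = 0.0123) and Reg3g from 5458 ± 2217 to 18103 ± 1874 CPM (1.73 ± 0.46, adjusted p = 0.0324). Of 11 antimicrobial genes 2 rose (3 higher adjusted over the list alone), and the list had a median of 0.21 (camera adjusted p = 0.163, adjusted p = 0.763 with an estimated correlation). Fut2 rose from 1.89 ± 0.434 to 46.5 ± 23.0 CPM (4.62 ± 0.50, adjusted p = 8.5e-05) and Gml2 from 2.08 ± 0.796 to 47.0 ± 7.54 CPM (4.50 ± 0.67, adjusted p = 0.00056). The chemokine Ccl20 rose from 1.25 ± 0.0931 to 5.74 ± 3.98 CPM (2.20 ± 0.60, adjusted p = 0.0343). Of 13 enteroendocrine genes 5 rose (9 higher adjusted over the list alone), with ghrelin (Ghrl) at 17.1 ± 5.21 against 5.74 ± 1.28 CPM. They had a median of 0.90 (camera adjusted p = 6.6e-06, adjusted p = 0.409 with an estimated correlation). Of 19 cholesterol synthesis genes 5 rose (13 higher adjusted over the list alone), and these had a median of 1.45 (camera adjusted p = 6.6e-06, adjusted p = 0.763 with an estimated correlation). Ccl24, an eosinophil chemokine, fell from 12.2 ± 6.74 to 0.692 ± 0.517 CPM (-4.15 ± 0.68, adjusted p = 0.00152). Mbl2 fell from 44.0 ± 6.11 to 3.68 ± 2.55 CPM and the vitamin B12 receptor Cubn from 522 ± 203 to 57.3 ± 32.6 CPM.

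Markers of position along the gut differed between CBLB502 and control as well. Of 9 proximal small intestine genes 4 rose (5 higher and 1 lower adjusted over the list alone), and they had a median of 1.19 (camera adjusted p = 0.0135, adjusted p = 0.763 with an estimated correlation). The iron genes Cybrd1 and Slc40a1 stood at 191 ± 253 against 1.00 ± 0.68 CPM and 453 ± 438 against 4.01 ± 1.67 CPM, and Pdx1 at 32.3 ± 23.0 against 0.778 ± 0.553 CPM. Macrophage genes had a median of -1.19 (camera adjusted p = 0.0117, adjusted p = 0.763 with an estimated correlation), with 1 of 12 fallen (3 adjusted over the list alone). Paneth cell genes had a median of -1.29 (camera adjusted p = 0.0178, adjusted p = 0.799 with an estimated correlation), with 0 of 17 called. In all 638 genes were called (276 higher, 362 lower). Without control replicate 1 or 2 the count was 176 and 286, and without CBLB502 replicate 1 or 2 351 and 189. It was 60 with the proximal score as a covariate and 56 with the 6 libraries fitted alone. With limma on log2(FPKM + 1) it was 349, of which 29.2% were higher instead of 43.3%, and with DESeq2 1129.

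**Figure D5:**
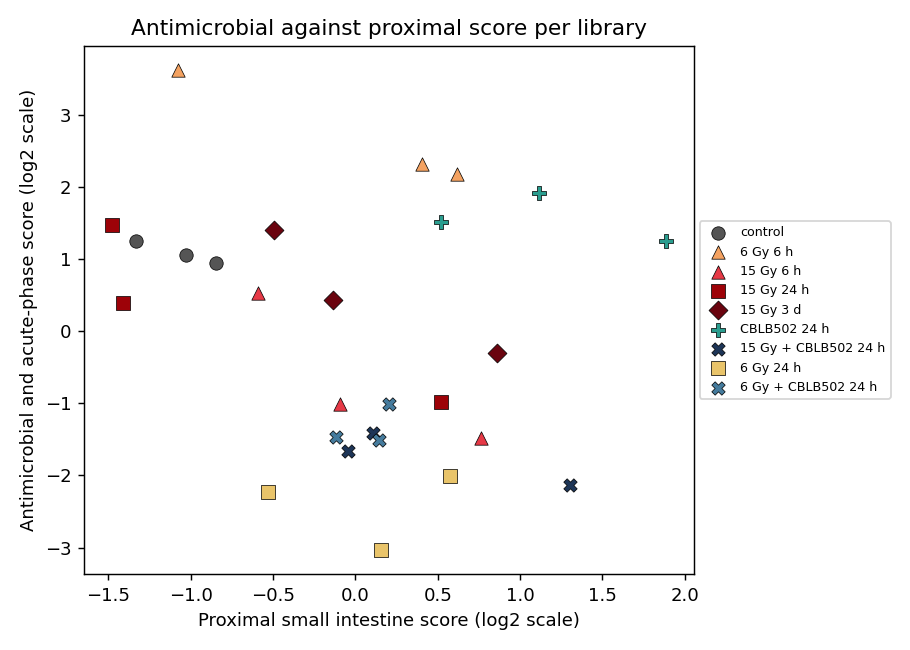
Score of the antimicrobial list against that of the proximal small intestine list (mean centred log2 CPM), 1 point per library, coloured by group. Group means of the antimicrobial score run from -2.42 ± 0.54 (6 Gy 24 h) to 2.70 ± 0.80 (6 Gy 6 h).

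Whether CBLB502 changed the tissue at 24 h after 15 Gy was asked by setting treated against untreated 15 Gy libraries. Here edgeR called 0 of 11118 genes, with 867 at an unadjusted p under 0.05, while DESeq2 called 63 and limma 0. Duox2 stood at 1.61 ± 0.406 against 86.6 ± 75.1 CPM (-5.74 ± 1.16, adjusted p = 0.167) and Nos2 at 0.273 ± 0.298 against 95 ± 129 CPM (-8.42 ± 1.74, adjusted p = 0.167). The NF-kB inhibitor Nfkbia stood at 26.0 ± 2.37 against 49.9 ± 23.0 CPM (-0.94 ± 0.24, adjusted p = 0.256). As a list, antimicrobial genes were lower (4 lower adjusted over the list alone) and had a median of -0.75 (camera adjusted p = 0.00026, adjusted p = 0.391 with an estimated correlation). The NF-kB list (3 lower adjusted over the list alone) had a median of -0.25 (camera adjusted p = 0.0215, adjusted p = 0.391 with an estimated correlation). Paneth cell genes had a median of -0.62 (camera adjusted p = 0.00339, adjusted p = 0.699 with an estimated correlation). Interferon-stimulated genes had a median of 0.43 (camera adjusted p = 0.00023, adjusted p = 0.699 with an estimated correlation). Proximal small intestine genes had a median of 0.87 (camera adjusted p = 0.00044, adjusted p = 0.391 with an estimated correlation). T cell genes had a median of 0.54 (camera adjusted p = 0.001, adjusted p = 0.699 with an estimated correlation). DNA replication genes had a median of 0.39 (camera adjusted p = 0.00397, adjusted p = 0.391 with an estimated correlation). PPAR-alpha genes of fat oxidation had a median of 0.46 (camera adjusted p = 0.00026, adjusted p = 0.391 with an estimated correlation). Without replicate 2 of 15 Gy 24 h edgeR called 93 genes, and without replicate 1 of 15 Gy with CBLB502 3.

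Against control, the libraries of 15 Gy with CBLB502 had 1874 called genes (962 higher, 912 lower). Of 11 antimicrobial genes 6 fell, and they had a median of -1.49 (camera adjusted p = 0.00642, adjusted p = 0.309 with an estimated correlation). Duox2 fell from 204 ± 99.7 to 1.61 ± 0.406 CPM (-6.98 ± 1.22, adjusted p = 0.0008) and Reg3g from 5458 ± 2217 to 1647 ± 553 CPM (-1.73 ± 0.46, adjusted p = 0.0135). Of 26 targets of p53 16 rose and 1 fell (18 higher and 2 lower adjusted over the list alone), and these had a median of 0.67 (camera adjusted p = 1.5e-08, adjusted p = 0.0169 with an estimated correlation). Cdkn1a fell (-0.68 ± 0.18, adjusted p = 0.0137). The water channel gene Aqp8 was at least 679-fold higher, at 9.86 ± 3.58 CPM against 0 counts. Nfkbia fell (-1.41 ± 0.24, adjusted p = 0.00067), and the NF-kB list had a median of -0.63 (camera adjusted p = 0.00642, adjusted p = 0.219 with an estimated correlation). The clock list had a median of -1.43 (camera adjusted p = 0.0182, adjusted p = 0.219 with an estimated correlation), with Arntl at 40.6 ± 19.5 against 4.11 ± 1.02 CPM. The count was 1127 without control replicate 1, 1213 with the 6 libraries fitted alone and 818 with the proximal score as a covariate. Among calls by limma on log2(FPKM + 1) 74.3% were higher instead of 51.3%, while the median of all genes moved by 0.12. The majority was lower with median-ratio scaling (1033 of 1921), DESeq2 (1305 of 2432) and the 6 libraries fitted alone (683 of 1213).

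The interaction asked whether CBLB502 acts differently with and without 15 Gy, and 25 genes were called (17 higher, 8 lower). For Fut2 it was -5.48 ± 0.66, adjusted p = 0.00055. CBLB502 raised Fut2 from 1.89 ± 0.434 to 46.5 ± 23.0 CPM without radiation, and at 15 Gy it stood at 2.25 ± 1.01 without and 1.24 ± 0.356 CPM with CBLB502. Gml2 (-5.24 ± 0.88, adjusted p = 0.0118) and Gml (-4.76 ± 0.99, adjusted p = 0.0432) also had negative values. Ccl24, lower with CBLB502 alone, stood at 6.76 ± 3.87 CPM at 15 Gy and 9.59 ± 4.0 CPM with CBLB502 (4.65 ± 0.89, adjusted p = 0.0266). Antimicrobial genes (6 lower adjusted over the list alone) had a median of -2.75 (camera adjusted p = 9.3e-06, adjusted p = 0.24 with an estimated correlation). Interferon-stimulated genes (9 higher adjusted over the list alone) had a median of 1.19 (camera adjusted p = 1.6e-11, adjusted p = 0.651 with an estimated correlation). Leaving out 1 library moved this count from 7 (replicate 3 of 15 Gy with CBLB502) to 48 (control replicate 3 or replicate 2 of 15 Gy 24 h). It was 11 and 8 without control replicate 1 or 2, and 8 and 9 without replicate 1 or 3 of 15 Gy 24 h. It was 18 and 12 without replicate 1 or 2 of 15 Gy with CBLB502, and 16, 15 and 22 without CBLB502 replicate 1, 2 or 3. It was 4 with the 12 libraries fitted alone, 61 with the proximal score as a covariate and 128 with DESeq2.

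For CBLB502 at 6 Gy, edgeR called 0 of 11118 genes at 24 h, with 303 at an unadjusted p under 0.05. DESeq2 called 7 and limma on log2(FPKM + 1) 9. Reg3g stood at 1930.3 ± 301 against 846 ± 276 CPM (1.19 ± 0.46, adjusted p = 1) and Isg15 at 53.6 ± 20.2 against 110.5 ± 66.7 CPM (-1.04 ± 0.51, adjusted p = 1). As lists, interferon-stimulated genes had a median of -0.62 (camera adjusted p = 2.4e-08, adjusted p = 0.63 with an estimated correlation). T cell genes had a median of -0.52 (camera adjusted p = 0.00015, adjusted p = 0.732 with an estimated correlation). PPAR-alpha genes (2 lower adjusted over the list alone) had a median of -0.18 (camera adjusted p = 7.2e-05, adjusted p = 0.535 with an estimated correlation). Antimicrobial genes had a median of 0.90 (camera adjusted p = 0.00477, adjusted p = 0.535 with an estimated correlation). Crypt stem cell genes had a median of 0.38 (camera adjusted p = 0.00592, adjusted p = 0.535 with an estimated correlation). Glucocorticoid-induced genes had a median of 0.57 (camera adjusted p = 0.00748, adjusted p = 0.63 with an estimated correlation). Macrophage genes had a median of 0.58 (camera adjusted p = 0.0377, adjusted p = 0.874 with an estimated correlation). The pancreatic list had a median and mean below 0 (median -0.96) while camera gave it the upward direction (adjusted p = 0.00592, adjusted p = 0.874 with an estimated correlation). Its libraries differed widely: Cela1 stood at 91.4 ± 67.6 against 165 ± 269 CPM, and replicate 2 of 6 Gy 24 h held 475.5 CPM where the other libraries of that group held 9.50 and 10.1 CPM. Without that library the change of Cela1 turned from -0.85 to 3.23. The list's adjusted p was then 3.7e-36, and without replicate 1 of 6 Gy 24 h it was 0.846 in the other direction. It was 0.869 without replicate 3 of 6 Gy 24 h, and 0.108 and 0.445 without replicate 1 or 3 of 6 Gy with CBLB502. As for calls, edgeR gave 2 without replicate 2 of 6 Gy 24 h, and 1 without replicate 3 of that group or replicate 2 of 6 Gy with CBLB502.

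Against control, the libraries of 6 Gy with CBLB502 had 4143 called genes (2198 higher, 1945 lower). They are also among the 6 that stood apart, so treatment cannot be told apart here from a batch or from tissue make-up. Of 13 crypt stem cell genes 7 rose, with Slc12a2 at 24.4 ± 9.05 against 3.11 ± 1.51 CPM. They had a median of 1.32 (camera adjusted p = 0.0099, adjusted p = 0.312 with an estimated correlation). Of 10 mitosis genes 6 rose (9 higher adjusted over the list alone), and the list had a median of 1.96 (camera adjusted p = 0.00702, adjusted p = 0.565 with an estimated correlation). DNA replication genes had a median of 0.86 (camera adjusted p = 0.0099, adjusted p = 0.312 with an estimated correlation). Of 17 Paneth cell genes 9 rose, and they had a median of 2.90 (camera adjusted p = 0.0131, adjusted p = 0.654 with an estimated correlation). Enterocyte genes had a median of -0.68 (camera adjusted p = 1.1e-06, adjusted p = 0.113 with an estimated correlation). Of 27 interferon-stimulated genes 12 fell, with Zbp1 at 31.5 ± 7.66 against 120.2 ± 14.8 CPM. These had a median of -0.98 (camera adjusted p = 0.00012, adjusted p = 0.565 with an estimated correlation). All 16 pancreatic genes (median 11.61 with 8 at their bound) and all 3 fibroblast genes tested, of 16 listed, were higher in the same libraries. Here too a gene high only in the libraries that stood apart passes the filter. With limma on log2(FPKM + 1) 6565 genes were called, 93.2% of them higher, while the median of all genes moved by 0.40. DESeq2 and median-ratio scaling gave a lower majority (2296 of 4515 and 2136 of 4170).

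At 6 Gy the interaction gave 36 genes (27 higher, 9 lower). Fut2 was negative (-4.31 ± 0.66, adjusted p = 0.0169), at 0.971 ± 0.25 CPM after 6 Gy and 1.21 ± 0.567 CPM with CBLB502. Ccl24 (4.69 ± 0.89, adjusted p = 0.0239), Bco1 (4.05 ± 0.85, adjusted p = 0.0411) and Cubn (3.71 ± 0.74, adjusted p = 0.0313) were positive. All 3 fell with CBLB502 alone, and Bco1 was already at 1.06 ± 0.251 CPM after 6 Gy against 42.4 ± 1.57 CPM in control. Slc11a2, an iron importer (-3.97 ± 0.80, adjusted p = 0.0313), stood at 648 ± 795 CPM with CBLB502. This count was 82 without control replicate 3, 59 without CBLB502 replicate 3 and 0 without replicate 3 of 6 Gy with CBLB502. It was 12 without control replicate 1 or 2, and 1 and 11 without CBLB502 replicate 1 or 2. It was 2, 44 and 10 without replicate 1, 2 or 3 of 6 Gy 24 h, and 26 and 11 without replicate 1 or 2 of 6 Gy with CBLB502. With the proximal score as a covariate it was 0, with the mitochondrial share 73 (44 higher), with DESeq2 158 (79 higher, 79 lower), and 11 with the 12 libraries fitted alone.

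Of 149 list calls by camera with the preset correlation, 4 held with an estimated correlation. These were enterocyte genes at 6 Gy 6 h against control and at 15 Gy against 6 Gy at 6 h, and p53 targets at 15 Gy 24 h, with and without CBLB502, against control.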

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

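The counts of splits were planned before the data were examined, and the splits within radiation levels and the tests of the 3 patterns below were chosen after results were seen. The effect of CBLB502 differed with and without radiation for 25 genes at 15 Gy and 36 at 6 Gy, by a test of the difference itself. At 15 Gy the values were Fut2 -5.48, Gml2 -5.24, Gml -4.76 and Cpe -2.02. Positive values were Ccl24 4.65, Ccne2 2.52, Plbd1 2.46, Slc5a4b 2.40, Lgals3bp 2.28, Slc28a1 1.95 and Abcg5 1.40. At 6 Gy they were Fut2 -4.31, Slc11a2 -3.97, Zfpm1 -2.21 and Oit1 -1.03, and Ccl24 4.69, Bco1 4.05, Cubn 3.71, Tns4 3.48, Abca1 2.87, Plbd1 2.56 and Abcg5 1.35. Among 100 splits over the 4 groups, 10 gave as many genes as the 15 Gy interaction and 12 as many as the 6 Gy interaction (highest other 962 and 3428), but such splits let the effect of radiation enter the term. Among 100 splits within radiation levels 9 and 5 did (highest other 649 and 384), and all of these left the groups without radiation whole, so that the effect of CBLB502 alone enters. Neither kind of split decides whether chance gives these counts. With 1 library left out the counts ran from 7 to 48 and from 0 to 82.

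In the 14 comparisons of 2 groups the 6 libraries make 10 splits, too few for a share under 0.05. Real and highest other counts against control were 3163 and 2 (6 Gy 6 h), 3219 and 2 (15 Gy 6 h), 3669 and 2 (6 Gy 24 h), 549 and 225 (15 Gy 24 h), and 3273 and 1 (15 Gy 3 d). They were 638 and 9 for CBLB502, 1874 and 1 with 15 Gy, and 4143 and 2 with 6 Gy. CBLB502 in irradiated mice gave 0 and 9 (15 Gy) and 0 and 7 (6 Gy). Between doses they were 4800 and 6 at 6 h and 1736 and 2 at 24 h, and between times 3575 and 7 (24 h and 6 h) and 2813 and 0 (3 d and 24 h).

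The first pattern weighed is that the 6 libraries of 6 Gy at 24 h lie apart from the rest. Pancreatic tissue would make the 760 genes higher in both groups follow the pancreatic score. That score ran from 3.06 to 9.67 among the 6, but the median slope of these genes was -0.0244 (quartiles over genes -0.0578 and 0.00719). A lower share of enterocytes would raise other cell types alike. Fibroblast and smooth muscle genes were 3.58 above goblet, tuft and enteroendocrine genes. The interval of 0.748 to 6.41 comes from an SE of 1.42 over resampled genes and does not measure the spread between libraries. Only 3 of 16 fibroblast and 9 of 14 smooth muscle genes were tested, and a gene high only in these 6 libraries passes the filter. The Paneth list, called higher at 6 Gy 24 h, was not in this test, so the test does not decide on the share of enterocytes. A separate library batch cannot be told apart from the groups, because batch and group coincide. Among the other libraries, 0 had a lincRNA share as high as the lowest of the 6 (0.239%), and TMM factors were 1.23 to 1.43 against 0.71 to 1.09.

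The second pattern is that 15 Gy at 6 h was unlike 6 Gy at 6 h, in 2244 genes called between the doses with a change of at least 2-fold, clock genes left out, whose signed median at 6 Gy 6 h against control was 0.784. Time of day would carry them along in 15 Gy with CBLB502 at 24 h. The clock score there differs from control as that of 6 Gy 6 h does. But the median of these genes there was 0.132 (0.101 to 0.161, a 95% interval over resampled genes, not libraries). With the clock score as a covariate 1446 (64.4%) were still called in the same direction, at 0.957 of their fold. But its slope rests on the spread within groups, widest at 15 Gy 24 h (SD 2.55), while the 6 h groups differ by -4.96. The libraries of 15 Gy with CBLB502 also carry effects of their own, so time of day is not decided. With the mitochondrial share as a covariate 1883 (83.9%) were still called in the same direction. The slope of that share also rests on the spread within groups, widest with CBLB502 alone (SD 8.59%). The 6 h groups stood at 19.7% (6 Gy) and 6.82% (15 Gy), so the mitochondrial share is not decided either. Position along the intestine was left undecided: 2228 stayed called with the proximal score as a covariate, but that score differed between the groups by 0.044 (SE 0.664), too little to remove them. Of all 4800 calls between the doses, 3537 were still called in the same direction with the mitochondrial share. Dose, which the design names, stays open and untested apart from other differences between the 2 groups.

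The third pattern is that the antimicrobial list had opposite medians for CBLB502 with and without 15 Gy. Camera did not call the list for CBLB502 alone, and edgeR called 0 genes for CBLB502 at 15 Gy. The median interaction was -2.75 (quartiles -4.87 and -0.25, 11 genes). Position along the intestine, time of day and 1 library were tested as sole causes. The median was -2.24 without replicate 1 of 15 Gy 24 h, the library that brought it nearest to 0 of the 12 left out in turn, so 1 library is argued against. The median was -2.85 with the proximal score as a covariate and -2.71 with the clock score. Within groups the antimicrobial score fell as the proximal score rose (slope -0.789). The interaction of the proximal score was -0.998 (SE 0.888), which by that slope would raise the list, against the pattern. But this value is not told apart from 0, and the slope was found on the same data. Position as this score measures it is therefore not decided as the sole cause. The interaction of the clock score was 0.225 (SE 1.79), too uncertain to decide, so time of day stays open. A response to CBLB502 that depends on radiation stays open too, and the list call was lost with an estimated correlation (adjusted p = 0.24).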

How the results depend on the processing

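Limma on log2(FPKM + 1) was the test of the plan and became an alternative when edgeR replaced it. Chosen after seeing the data were DESeq2, the covariates, the mitochondrial genes left out and the fit without the 6 libraries of 6 Gy at 24 h. With 3 libraries per group, simulated 2-fold changes at 15 Gy 24 h were recovered for 55.2% of genes by edgeR. Of 692 called results of named genes, 369 kept direction and side of the threshold in all settings. Of 149 list calls 71 did in all settings other than the estimated correlation, with which 4 held. The cause was not tested unless said. The median of all genes moved by 0.38, 0.40 and -0.33 for 6 Gy 24 h vs control, 6 Gy + CBLB502 24 h vs control and 15 Gy 24 h vs 6 Gy 24 h with limma on log2(FPKM + 1). With log2(FPKM + 0.1) it moved by 0.55, 0.58 and -0.45.

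Shares of calls that were higher also moved with the scaling. With limma on log2(FPKM + 0.1) they were 72.9% for 15 Gy 3 d and 74.5% for 15 Gy + CBLB502 vs control, while the median of all genes moved by 0.24 and 0.19. They were 61.5% for 15 Gy 3 d vs 24 h (median moved by 0.13), 63.7% for 15 Gy 24 h vs control (median moved by 0.11), 68.6% for 15 Gy 24 h vs 6 h and 30.9% for CBLB502 vs control. The share was 55.2% for 6 Gy 6 h vs control. Against control the majority of calls turned to lower with DESeq2 and median-ratio scaling in 4 comparisons. For 15 Gy 24 h they gave 488 higher and 583 lower, and 255 and 277. For 6 Gy 24 h they gave 1958 and 2147, and 1716 and 1972. For 15 Gy + CBLB502 they gave 1127 and 1305, and 888 and 1033. For 6 Gy + CBLB502 they gave 2219 and 2296, and 2034 and 2136. With the compared groups alone 383 of 1532 were higher for 15 Gy 6 h vs control and 14 of 56 for CBLB502 vs control.

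Counts of calls: with no filter on low values 262 for 15 Gy 24 h vs control, 350 for CBLB502 24 h vs control, 1 for 15 Gy + CBLB502 24 h vs 15 Gy 24 h, 1143 for 15 Gy 24 h vs 6 Gy 24 h and 22 for the 6 Gy interaction. With limma on log2(FPKM + 1) they were 2133 for 15 Gy 6 h vs control, 6241 for 6 Gy 24 h vs control, 241 for 15 Gy 24 h vs control and 349 for CBLB502 24 h vs control. In that setting 9 were called for 6 Gy + CBLB502 24 h vs 6 Gy 24 h, 6565 for 6 Gy + CBLB502 24 h vs control and 4449 for 15 Gy 24 h vs 6 Gy 24 h. Limma on log2(FPKM + 0.1) gave 6112, 306, 391, 6412 and 4053 for 6 Gy 24 h, 15 Gy 24 h, CBLB502 and 6 Gy + CBLB502 vs control and 15 Gy 24 h vs 6 Gy 24 h. Quantile-normalized values gave 362 for 15 Gy 24 h vs control and 10 for 6 Gy + CBLB502 24 h vs 6 Gy 24 h. DESeq2 gave 1071 for 15 Gy 24 h and 1129 for CBLB502 vs control, 63 and 7 for CBLB502 at 15 Gy and 6 Gy, and 128 and 158 for the interactions. With the mitochondrial share as a covariate they were 824 for 15 Gy 24 h vs control and 73 for the 6 Gy interaction. With the proximal score they were 60 for CBLB502 and 818 for 15 Gy + CBLB502 vs control, and 61 and 0 for the interactions. Without the 6 libraries of 6 Gy at 24 h they were 292 for 15 Gy 24 h and 412 for CBLB502 vs control. Fitted with the compared groups alone, which leaves fewer libraries to estimate the spread, the counts against control were 1532 (15 Gy 6 h), 12 (15 Gy 24 h), 2142 (15 Gy 3 d), 56 (CBLB502) and 1213 (15 Gy + CBLB502). Between treated groups they were 1 (6 Gy + CBLB502 vs 6 Gy 24 h), 307 (15 Gy vs 6 Gy 24 h), 2024 (15 Gy 24 h vs 6 h), 1663 (3 d vs 24 h), and 4 and 11 for the interactions.

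With each library left out, counts ran from 216 to 629 for 15 Gy 24 h vs control, 176 to 779 for CBLB502 vs control and 1127 to 1996 for 15 Gy + CBLB502 vs control. They ran from 714 to 1870 for 15 Gy 24 h vs 6 Gy 24 h, 0 to 93 and 0 to 2 for CBLB502 at 15 Gy and 6 Gy, and 7 to 48 and 0 to 82 for the interactions. The adjusted p of the pancreatic list for 6 Gy + CBLB502 vs 6 Gy 24 h ran from 3.72e-36 to 0.869 and was 0.846 in the other direction without replicate 1 of 6 Gy 24 h. Cela1 ran from -1.45 to 3.23.

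A fit with the replicate number as a replicate block gave 1 call for 6 Gy + CBLB502 24 h vs 6 Gy 24 h and 21 for the 6 Gy interaction. The numbers do not pair the libraries: 10 of 42 pairs had a correlation over 0.1 (-0.262 to 0.248), 15 were best with their own number, and 0 comparisons had all pairs over 0.1.

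Reversed directions, with the range of the camera adjusted p over the alternatives: with limma on log2(FPKM + 1) the pancreatic list at 15 Gy 24 h vs control (0.866, range 0.00016 to 0.866). With that setting Mdm2 was 0.35 and 0.34 at 6 Gy 24 h and 6 Gy + CBLB502 vs control, and 0.39 and 0.38 with log2(FPKM + 0.1). Quantile normalization reversed the mitochondrial genome at 6 Gy 24 h vs control (0.341, range 6.5e-05 to 0.729). It did so at 6 Gy + CBLB502 vs control (0.392, range 4e-06 to 0.601) and 15 Gy vs 6 Gy 24 h (0.484, range 1.9e-09 to 0.576). It reversed enterocyte genes at 15 Gy vs 6 Gy 24 h (0.789, range 1.1e-08 to 0.789). Single genes there were mt-Co2 0.10 and mt-Atp8 0.28 (6 Gy + CBLB502 vs control), and Apoa4 -0.40 and mt-Co2 -0.12 (15 Gy vs 6 Gy 24 h). The mitochondrial share reversed the mitochondrial genome at 15 Gy vs 6 Gy 6 h (0.945, range 0.0001 to 0.945). The proximal score, built from the proximal list, reversed Paneth genes at CBLB502 vs control (0.242, range 0.00088 to 0.799). It did so at 15 Gy + CBLB502 vs 15 Gy 24 h (0.927, range 1.3e-05 to 0.927) and in the 6 Gy interaction (0.731, range 5.6e-05 to 0.731). Proximal genes reversed at CBLB502 vs control (0.407, range 0.00062 to 0.763) and in the 6 Gy interaction (0.522, range 0.00025 to 0.68), and Slc40a1 was -0.36.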

Other observations

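The test in the last paragraph was chosen after its pattern was seen, and the comparisons in the others are lists and correlations not described above. With CBLB502 alone, interferon-stimulated genes had a median of -0.69 (camera adjusted p = 6.9e-05, adjusted p = 0.763 with an estimated correlation) against control. Plasma cell genes had a median of -2.11 (camera adjusted p = 0.0288, adjusted p = 0.763 with an estimated correlation) there. At 15 Gy 24 h against control, cholesterol synthesis genes had a median of -0.49 (camera adjusted p = 0.00432, adjusted p = 0.816 with an estimated correlation). DNA repair genes had a median of 0.57 (camera adjusted p = 0.0149, adjusted p = 0.408 with an estimated correlation) in that comparison. From 24 h to 3 d after 15 Gy, crypt stem cell genes had a median of 0.88 (camera adjusted p = 0.00125, adjusted p = 0.205 with an estimated correlation). The 3 neutrophil genes tested, of 15 listed, had a median of 2.88 (camera adjusted p = 0.00259, adjusted p = 0.104 with an estimated correlation) over the same days.

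Changes could be compared without shared libraries for a few pairs of comparisons. Genes higher at 15 Gy than at 6 Gy at 6 h were often lower at 3 d than at 24 h after 15 Gy (800 against 317.6 by chance, Spearman rho -0.278 over 11118 genes). The effect of CBLB502 alone and its effect at 15 Gy had a rho of 0.313, and with its effect at 6 Gy the rho was 0.064. The proximal score was also higher with CBLB502 alone (1.17 ± 0.68 against -1.07 ± 0.24) and at 15 Gy (0.45 ± 0.74 against -0.79 ± 1.14). At 6 Gy it was 0.08 ± 0.17 against 0.07 ± 0.56. A shared difference in position is therefore not set apart from a shared effect of CBLB502. The effects of CBLB502 at the 2 doses had a rho of -0.111.

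Within groups, the antimicrobial score was lower where the proximal small intestine score was higher (Pearson r = -0.779 over 27 libraries centred on their group means, permutation p = 0.00093, 100000 permutations). Spearman rho was -0.747 (permutation p = 0.00112). Without the 2 farthest libraries, replicate 2 of 15 Gy 24 h and replicate 1 of 6 Gy 6 h, r was -0.691, and without the 6 libraries apart it was -0.856. Sampling at different positions along the intestine may account for part of the spread between replicates, as a hypothesis found and tested on the same data.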
